A study of Mus musculus with 20 samples.

How the data were processed

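The deposited table held 45101 probe sets of the Mouse 430 2.0 array for 20 arrays, 1 per liver and 5 individual livers for each of 2 genotypes on 2 diets per the series design. Values were taken as intensity on a linear scale, judged from the deposited numbers. MAS5 and RMA are named per the submitters' processing notes; which of them made the values, and with which version, is not given in the sources used here. Total RNA came from flash-frozen liver and was labelled as biotinylated cRNA per the labels. Age, sex, feeding time and length of diet are not given in the sources used here. Sex was read only from X- and Y-linked genes, given under other observations.

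Groups, tests, gene lists and alternatives were set before the data were examined, except where a test is said to have been chosen after a result was seen. Arrays were scaled to a common median, floored at 16, log2-transformed and quantile-normalized. After removal of 64 control probe sets 45037 were tested; 9117 of these lay at the floor on all 20 arrays, stayed out of the variance model and counted as unchanged in the adjustment. Another 6688 lay at the floor on some arrays, where fold changes are lower bounds. A mean per group was fitted by limma 3.58.1 in R 4.3.3 (residual degrees of freedom 16, prior 1.94), with empirical Bayes statistics and Benjamini-Hochberg adjustment over all tested probe sets. A call means an adjusted p under 0.05, and ± in log2 is the standard error of the estimate. The number of arrays limits the precision of each estimate.

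Probe sets were matched to genes by the probe table: 34945 named a single gene, 932 several and 9160 none. Each of 18193 genes was read from its brightest probe set by mean log2 value; 9010 had several probe sets and 2006 lay at the floor everywhere, which left 16187 measurable genes. Of called genes with other probe sets, 321 of 4388 had another probe set called in the opposite direction for knockout versus wild type on the VLF diet, 164 of 3654 for the diet in knockout, 65 of 2538 for the interaction, 553 of 5057 for knockout on the VLF diet versus wild type on chow, and 0 of 316 and 0 of 160 for knockout versus wild type on chow and the diet in wild type (limma calls). Gene sets were 38 fixed lists with 706 genes, 615 of them measured, tested without Scd1 by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 38 lists of a comparison.

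Genes were named by a rule set in advance: the 6 largest called rises and falls without overlap between groups (for the interaction and the set found only in the knockout on the VLF diet the 6 largest called each way), up to 4 members per list with the smallest adjusted p, and 13 preset genes, of which 11 were measured; the others were not analysed here. Some genes that go against their list's direction, or that make up a count of 5 or fewer, are also named and were chosen after their values were seen. In simulated data with the arrays' own spread, known changes of log2 0.5, 1 and 2 were recovered in 53.7%, 93.8% and 95.6% of probe sets for knockout versus wild type on the VLF diet (5 false calls of 200), and in 28.4%, 84.6% and 94.1% for the interaction (5 false of 155). The changed probe sets were drawn without the dimmest ones, and the noise was independent between probe sets. Only 67, 65 and 68 probe sets carried these changes, beside a shifted gene list. In the real arrays limma called 15059 probe sets between knockout and wild type on the VLF diet. The recovery and the false calls are therefore not shown to carry over to comparisons with that many changes. Arrays of a group differed by a mean of 0.117 to 0.227 in absolute log2 value per pair, and the largest principal component held 65.9% of the variance. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.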

Results

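Scd1 encodes the liver enzyme that turns saturated into monounsaturated fatty acids, and it is the gene removed in the knockout. Livers were compared in 4 groups of 5 mice each: wild type on chow, wild type on the very-low-fat (VLF) diet, knockout on chow and knockout on the VLF diet. Normalized Scd1 intensity averaged 8607 ± 1597 (mean ± SD, n = 5 livers) in wild-type chow livers and 18158 ± 1419 in wild-type VLF livers. In the knockout it averaged 45.9 ± 11.5 on chow and 31.5 ± 4.00 on the VLF diet, beside deposited array medians of 32.2 to 36.5 over all probe sets. Scd1 was 579-fold lower by the fitted change in the knockout on the VLF diet (log2 change -9.18 ± 0.16, estimate ± standard error, limma adjusted p = 3.94e-17) and 190-fold lower on chow (-7.57 ± 0.16, adjusted p = 1.22e-15). With knockout signal close to the array medians, the size of the Scd1 folds is limited by background. A dimmer Scd1 probe set was lower by 7.35 ± 0.28 on the VLF diet and 4.61 ± 0.28 on chow, at the floor in 9 of 10 knockout livers. Every genotype label was matched by the Scd1 level: the deposited values were 26 to 57 in all 10 knockout livers and 6522 to 20108 in all 10 wild-type livers. Diet labels of the knockout are not checked by Scd1, since its values overlapped (25.9 to 37.4 on the VLF diet, 27.2 to 57.4 on chow). Whether the probe set lies in the deleted part of the gene is not given in the sources used here.

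**Figure D1:**
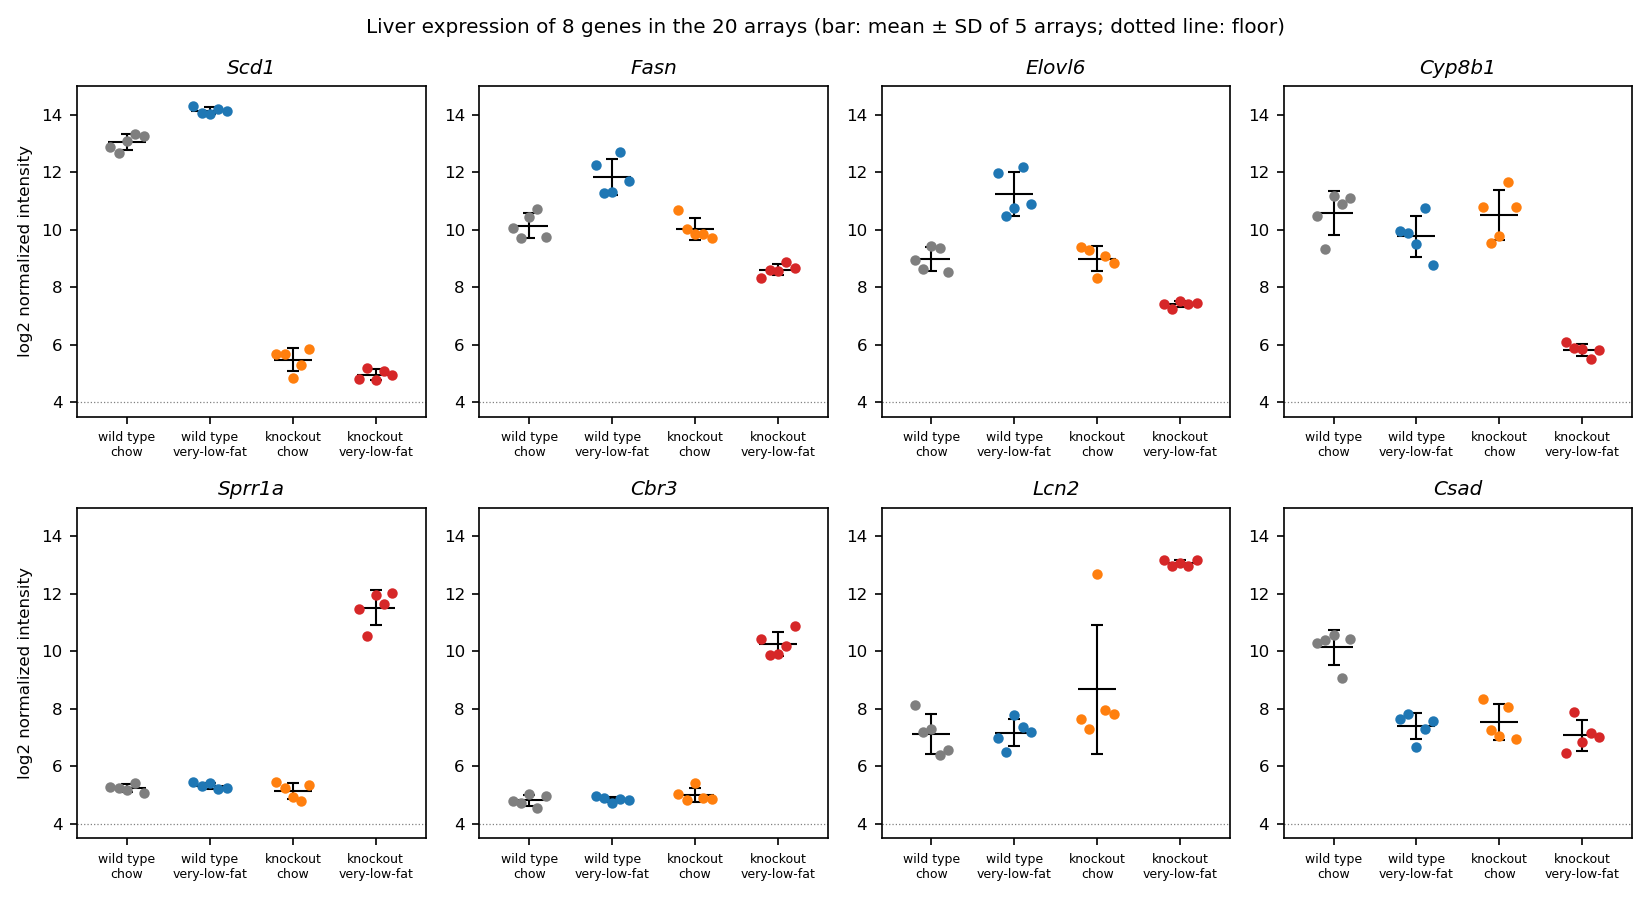
Normalized intensity on a log2 scale (y axis) in each liver of the 4 groups (x axis, n = 5 each) for Scd1, Fasn, Elovl6, Cyp8b1, Sprr1a, Cbr3, Lcn2 and Csad; bars are mean ± SD. The dotted line marks the floor at log2 = 4, and Scd1 averaged 18158 in wild-type and 31.5 in knockout VLF livers.

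On the VLF diet Sprr1a, Lcn2 and Cbr3 rose in the knockout liver and Fasn, Elovl6 and Cyp8b1 fell (n = 5 and 5 livers). Sprr1a, a squamous envelope protein of injured epithelia, rose 72.8-fold from 40.4 ± 3.0 to 3113 ± 1062 (log2 change 6.19 ± 0.20). Lcn2, a secreted iron-siderophore binder, rose 59.6-fold (5.90 ± 0.72), and Cbr3, a carbonyl reductase, rose 41.8-fold (5.38 ± 0.16). Sprr1a and Cbr3 started close to the array medians, so background limits the size of their folds in each comparison. Fasn, the fatty acid synthase, fell 9.40-fold from 3982 ± 1808 to 395 ± 55.0 (-3.23 ± 0.26), and Elovl6, which elongates palmitate, fell from 2743 ± 1465 to 171 ± 12.0 (-3.84 ± 0.29). Cyp8b1, the sterol 12-hydroxylase of cholic acid synthesis, fell from 968 ± 476 to 57.6 ± 8.2 (-3.94 ± 0.41).

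Of 18193 genes, 7670 changed between knockout and wild type on the VLF diet (42.2%; limma, Benjamini-Hochberg over 45037 probe sets), 3487 up and 4183 down. With arrays centred on the hybridization controls limma called 4356 up and 1003 down; read from the same probe sets, 3406 of the rises and 1000 of the falls were still called and 0 turned. Changes of 2-fold or more were found in 775 genes up and 542 down, and in 5480 genes the 5 knockout livers lay wholly outside the range of the 5 wild-type livers. Next to Sprr1a, Lcn2 and Cbr3 the largest rises were those of Cd14, the lipopolysaccharide co-receptor (33.1-fold, 5.05 ± 0.30), the estrogen sulfotransferase Sult1e1 (24.5-fold, 4.62 ± 0.51, with 2 of 5 wild-type values at the floor) and the lectin Lgals3 (24.5-fold, 4.61 ± 0.16). Next to Scd1 the largest falls were those of the sulfotransferase Sult3a1, at the floor in all 5 knockout livers (at least 80.3-fold, adjusted p = 7.06e-12), carbonic anhydrase Car3 (41.9-fold, -5.39 ± 0.32) and sulfotransferase Sult2a8 (35.8-fold, -5.16 ± 0.19). The corticosteroid-binding globulin Serpina6 fell 27.1-fold (-4.76 ± 0.27) and the urinary protein Mup10 fell 19.2-fold (-4.26 ± 0.24), with 3 of 5 knockout values at the floor. Among genes chosen in advance, Scd2 (1.84 ± 0.32) and Ppargc1a (1.59 ± 0.27) rose, while Srebf1 (-1.93 ± 0.17), Cyp7a1 (-2.29 ± 0.48), Slc10a1 (-1.89 ± 0.16), Abcb11 (-0.95 ± 0.17) and Cpt1a (-0.65 ± 0.12) fell. Pck1 was not called (-0.33 ± 0.14, adjusted p = 0.0845). The hepatokine gene Fgf21 rose by 0.62 ± 0.21 (adjusted p = 0.0251), a call that ended without knockout VLF array 1, 3 or 4 or wild-type VLF array 5 (adjusted p up to 0.0743).

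Of 26 measured fatty acid and triglyceride synthesis genes 21 fell, 3 rose and 2 were not called, with the same 21 and 3 adjusted over the list alone. Dgat2 (-1.73 ± 0.10), Elovl6, Fads2 (-2.23 ± 0.17) and Fasn fell, whereas the pentose phosphate genes Pgd (1.72) and Tkt (0.51) rose together with Scd2. That list fell as a set (camera adjusted p = 3.86e-06; adjusted p = 0.128 with an estimated correlation). In cholesterol synthesis 8 of 19 fell and 11 were not called, among them Sc5d (-1.80 ± 0.14), Stard4 (-1.93 ± 0.16), Ebp (-0.94 ± 0.09) and Tm7sf2 (-1.94 ± 0.22). The same 8 fell when adjusted over the list alone (camera adjusted p = 0.00959; adjusted p = 0.551 with an estimated correlation). Fatty acid oxidation and ketogenesis had 21 of 30 down, 3 up and 6 not called (22 down and 3 up adjusted over the list alone; median -0.59). Fabp1 (-1.53 ± 0.12), Eci1 (-1.35 ± 0.11), Hadh (-0.94 ± 0.08) and Cpt2 (-0.81 ± 0.07) fell, while Pdk4 (3.26), Acot2 (0.82) and Ehhadh (0.29) rose. Camera gave fatty acid oxidation adjusted p = 2.90e-05, and adjusted p = 0.351 with an estimated correlation. Peroxisomal genes fell in 17 of 22, with 5 not called and 18 down adjusted over the list alone, led by Hacl1 (-2.53 ± 0.13) and Slc27a2 (-1.42 ± 0.11). Camera gave peroxisomal genes adjusted p = 2.83e-07, and adjusted p = 0.0955 with an estimated correlation.

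Lipid handling and transport moved both ways. The lipid droplet and fatty acid uptake list had 11 up, 9 down and 6 not called of 26 (13 up and 10 down adjusted over the list alone; camera adjusted p = 0.309), with lipoprotein lipase Lpl (3.85 ± 0.20) and the droplet protein Cidea (2.66 ± 0.21) up and Fabp2 (-2.26 ± 0.17) down. Lipoprotein and cholesterol transport had 4 up, 9 down and 6 not called of 19 (4 up and 10 down adjusted over the list alone; camera adjusted p = 0.273): Apoa2 (-0.43 ± 0.04), Lcat (-0.61 ± 0.08) and Npc1 (-0.61 ± 0.08) fell, and Apoc2 (0.66) and Scarb1 (0.64) rose. LXR targets split 6 up and 5 down with 2 not called of 13 (the same adjusted over the list alone), with Lpl up and Pltp (-1.26) and Nr1h3 (-0.75) down; their median was -0.04, their mean 0.13 and the camera direction up (adjusted p = 0.83). In the stearoyl-CoA desaturase family, tested without Scd1, Scd2 rose (camera adjusted p = 0.641). Scd3 fell by 0.30, a call that ended without knockout VLF array 3 or wild-type VLF array 1 or 3 (adjusted p up to 0.103).

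Of 15 bile acid synthesis genes 12 fell, 1 (Acox2, 0.71) rose and 2 were not called (12 down and 2 up adjusted over the list alone), with Scp2 (-0.87 ± 0.05), Hsd3b7 (-1.31 ± 0.10), Slc27a5 (-1.34 ± 0.11) and Cyp8b1 lowest in adjusted p. Camera gave bile acid synthesis adjusted p = 0.000349, and adjusted p = 0.111 with an estimated correlation. Basolateral uptake transporters fell in 5 of 6 (6 adjusted over the list alone), led by Slco2b1 (-1.31 ± 0.10), Slco1b2 (-2.24 ± 0.17), Slc10a1 and Slc22a7 (-1.34 ± 0.24). Camera gave the uptake transporters adjusted p = 0.000852, and adjusted p = 0.111 with an estimated correlation. Basolateral efflux transporters rose in 4 of 5, and in 4 adjusted over the list alone: Abcc4 (3.18 ± 0.15), Slc51b (2.02 ± 0.14), Abcc1 (1.30 ± 0.09) and Abcc3 (1.12 ± 0.12). Camera gave the efflux transporters adjusted p = 0.000307, and adjusted p = 0.0225 with an estimated correlation. Canalicular export was mixed, with Abcc2 (1.39 ± 0.07), Abcb1a (1.78 ± 0.20) and Abcb4 (0.70 ± 0.11) among 4 up and Abcg8 (-0.94 ± 0.13) and Abcb11 among 3 down of 9, 2 not called (the same adjusted over the list alone). Its median was -0.01, its mean 0.23 and its camera direction up (adjusted p = 0.339).

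Glycolysis genes had 6 up, 3 down and 3 not called of 12 (7 up and 3 down adjusted over the list alone), with Pkm (1.86 ± 0.11), Aldoa (1.29 ± 0.16) and Hk2 (0.83 ± 0.11) up and Pklr (-1.36), Khk (-0.59) and Pfkl (-0.27) down. Its camera call (adjusted p = 0.0358; adjusted p = 0.153 with an estimated correlation) ended without knockout VLF array 1 (adjusted p = 0.0533). The glycolysis call also ended among brighter probe sets, with only the compared groups fitted and without probe sets that can read several transcripts. Gluconeogenesis had 4 up, 3 down and 6 not called of 13 (7 up and 4 down adjusted over the list alone; camera adjusted p = 0.313), with Igfbp1 (3.68 ± 0.47) and Irs2 (0.82 ± 0.15) up and Fbp1 (-0.87 ± 0.06) down. Urea cycle and amino acid catabolism genes fell in 16 of 26, 9 not called (17 down and 4 up adjusted over the list alone), led by Otc (-1.31 ± 0.07), Hpd (-1.29 ± 0.08) and Fah (-0.97 ± 0.07); Ass1 (0.70) rose. Camera gave urea cycle genes adjusted p = 0.000307, and adjusted p = 0.328 with an estimated correlation. Mitochondrial respiratory chain genes fell in 20 of 32, 1 (Cycs, 0.36) rose and 11 were not called (the same adjusted over the list alone), with Ndufb5 (-0.69 ± 0.05) and Etfa (-0.68 ± 0.05) down. Camera gave respiratory chain genes adjusted p = 1.05e-05, and adjusted p = 0.161 with an estimated correlation. Clock genes had 4 up, 6 down and 8 not called of 18 (4 up and 8 down adjusted over the list alone; camera adjusted p = 0.313); Dbp (-3.43 ± 0.31), Hlf (-1.20 ± 0.12) and Tef (-1.33 ± 0.18) fell, and Nfil3 (1.46), Cry1 (1.33) and Arntl (1.15) rose.

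NRF2 and glutathione genes rose in 16 of 20, fell in 2 and were not called in 2 (17 up and 2 down adjusted over the list alone): Cbr3, glutathione reductase Gsr (1.58 ± 0.05), sulfiredoxin Srxn1 (4.20 ± 0.18) and Gstm3 (2.93 ± 0.18) rose, and Gstt3 (-0.79) and Gstm6 (-0.45) fell. The list rose as a set (camera adjusted p = 1.60e-11; adjusted p = 0.00119 with an estimated correlation). In the ATF4 and amino acid response 16 of 21 rose, 2 fell and 3 were not called (the same 16 and 2 adjusted over the list alone), with serine synthesis enzyme Psat1 (3.94 ± 0.12), Atf3 (3.64 ± 0.14) and Slc3a2 (1.88 ± 0.12) up and Atf5 (-1.17) and Shmt2 (-0.58) down. Camera gave the ATF4 response adjusted p = 2.83e-07, and adjusted p = 0.0554 with an estimated correlation. ER chaperones rose in 17 of 21, 4 not called (19 adjusted over the list alone), led by Derl3 (2.06 ± 0.11), Pdia6 (1.02 ± 0.08) and Dnajc3 (1.40 ± 0.12). Camera gave ER chaperones adjusted p = 9.90e-09, and adjusted p = 0.0934 with an estimated correlation. Heat shock and immediate early genes rose in 14 of 19, fell in 2 and were not called in 3 (the same adjusted over the list alone), with Hspa1a (3.53 ± 0.15), Klf6 (2.19 ± 0.10) and Myc (2.33 ± 0.13) up and Hsph1 (-1.09) down. Camera gave heat shock genes adjusted p = 5.46e-07, and adjusted p = 0.0216 with an estimated correlation. The p53 and cell death list had 11 up, 2 down and 3 not called of 16 (the same adjusted over the list alone): Tnfrsf12a (3.37 ± 0.12), Cdkn1a (3.89 ± 0.29) and Trp53inp1 (2.23 ± 0.20) rose and Fas (-0.49) fell. Camera gave the p53 list adjusted p = 0.000174, and adjusted p = 0.0225 with an estimated correlation. Cell cycle genes rose in 21 of 25, 4 not called (22 adjusted over the list alone), among them Nusap1 (1.75 ± 0.14), Birc5 (2.60 ± 0.25) and Mcm2 (1.69 ± 0.17). Camera gave cell cycle genes adjusted p = 1.48e-09, and adjusted p = 0.0934 with an estimated correlation.

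Macrophage and Kupffer cell markers rose in 19 of 20 (20 adjusted over the list alone), with Gpnmb (3.93 ± 0.18), Ctss (2.12 ± 0.10), Cd68 (2.32 ± 0.13) and Cd14 lowest in adjusted p. Camera gave macrophage markers adjusted p = 4.84e-14, and adjusted p = 0.0216 with an estimated correlation. Stellate cell and fibrosis markers rose in 16 of 22, 1 (Lrat, -0.51) fell and 5 were not called (17 up and 1 down adjusted over the list alone), with Dcn (1.12 ± 0.07), Timp1 (1.54 ± 0.13) and Vim (1.87 ± 0.20) up. Camera gave stellate markers adjusted p = 3.86e-06, and adjusted p = 0.0934 with an estimated correlation. Cholangiocyte markers rose in 5 of 12, 7 not called (5 adjusted over the list alone), led by Anxa3 (1.51 ± 0.11), Cldn4 (1.57 ± 0.16) and Sox9 (1.16 ± 0.12). Camera gave cholangiocyte markers adjusted p = 0.0182, and adjusted p = 0.0989 with an estimated correlation. Interferon response genes rose in 10 of 17, 1 (Igtp, -0.71) fell and 6 were not called (the same adjusted over the list alone), with Oas1a (1.30 ± 0.13), Usp18 (2.14 ± 0.26) and Rsad2 (2.57 ± 0.33) up. Camera gave interferon response genes adjusted p = 0.00021, and adjusted p = 0.328 with an estimated correlation. Acute phase proteins rose in 15 of 25, fell in 6 and were not called in 4 (16 up and 6 down adjusted over the list alone): Cp (0.94 ± 0.08), Hpx (0.45 ± 0.05) and Hp (1.21 ± 0.14) rose, and Crp (-1.40 ± 0.10) and Saa4 (-1.55) fell. Camera gave acute phase proteins adjusted p = 0.00959, and adjusted p = 0.54 with an estimated correlation. Among neutrophil markers S100a8 (4.00 ± 0.51), S100a9 (3.16 ± 0.42) and Mmp8 (0.79 ± 0.16) rose (camera adjusted p = 0.0969). The call of Cxcr2 (-0.34) ended without knockout VLF array 1, 3 or 4 or wild-type VLF array 2, 3 or 5 (adjusted p up to 0.0922).

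Sinusoidal endothelial markers fell in 7 of 14, 1 (Lyve1, 2.45) rose and 6 were not called (the same adjusted over the list alone; camera adjusted p = 0.171). Of 14 lymphocyte markers limma called 0 adjusted over the list alone, with 3 at unadjusted p under 0.05 (camera adjusted p = 0.708). Ms4a1 (-0.37) and Cd4 (-0.19) were called over all probe sets, but not without wild-type VLF array 3 (adjusted p = 0.0518 and 0.116), and Cd4 not without knockout VLF array 1, 3 or 4 (up to 0.0881). In antigen presentation H2-D1 (0.55) and H2-DMa (0.30, but -0.10 with the mean of its probe sets) rose and Psmb9 (-0.53) fell, with a list median of -0.07, a mean of -0.05 and a camera direction of up (adjusted p = 0.959). H2-Eb1 (-0.32) lost its call without knockout VLF array 3 or 4 or wild-type VLF array 2, 3 or 5 (adjusted p up to 0.0874). Hepatocyte identity genes fell in 10 of 16, 1 (Ambp, 0.14) rose and 5 were not called (11 down and 2 up adjusted over the list alone). Camera gave hepatocyte identity genes adjusted p = 0.00801, and adjusted p = 0.111 with an estimated correlation. Drug-metabolizing P450 genes fell in 16 of 24, rose in 2 (Cyp2b10, 1.67; Ephx1, 1.43) and were not called in 6 (the same adjusted over the list alone), with Cyp2b9 (-3.45 ± 0.10) and Cyp2c37 (-3.23 ± 0.20) down. Camera gave the P450 list adjusted p = 2.94e-05, and adjusted p = 0.111 with an estimated correlation. All 12 female-biased liver genes fell, also adjusted over the list alone, among them Cyp2b13 (-3.67 ± 0.24), Cux2 (-3.02 ± 0.25) and Sult3a1. Camera gave female-biased genes adjusted p = 1.03e-07, and adjusted p = 0.0216 with an estimated correlation. Male-biased genes split, with Gstp1 (1.64 ± 0.09) and Cyp2d9 (3.46 ± 0.24) among 4 up and Nudt7 (-1.97 ± 0.11) and Mup3 (-2.62 ± 0.16) among 6 down of 12, 2 not called (the same adjusted over the list alone; camera adjusted p = 0.612). Of blood cell markers Car2 (-0.50 ± 0.11) and Alas2 (-1.02 ± 0.24) fell (camera adjusted p = 0.124), and of pancreas and fat markers Fabp4 (2.06) rose (camera adjusted p = 0.362). Of all 38 lists camera called 13 up and 11 down, and 6 of these 24 with an estimated correlation. The actin control's 3' to 5' ratio averaged 1.82 in the knockout VLF and 2.19 in the wild-type VLF arrays (difference -0.362, two-sided exact permutation p = 0.0159, n = 5 and 5). Arrays centred on the hybridization controls moved the median of all genes from -0.06 to 0.13.

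**Figure D2:**
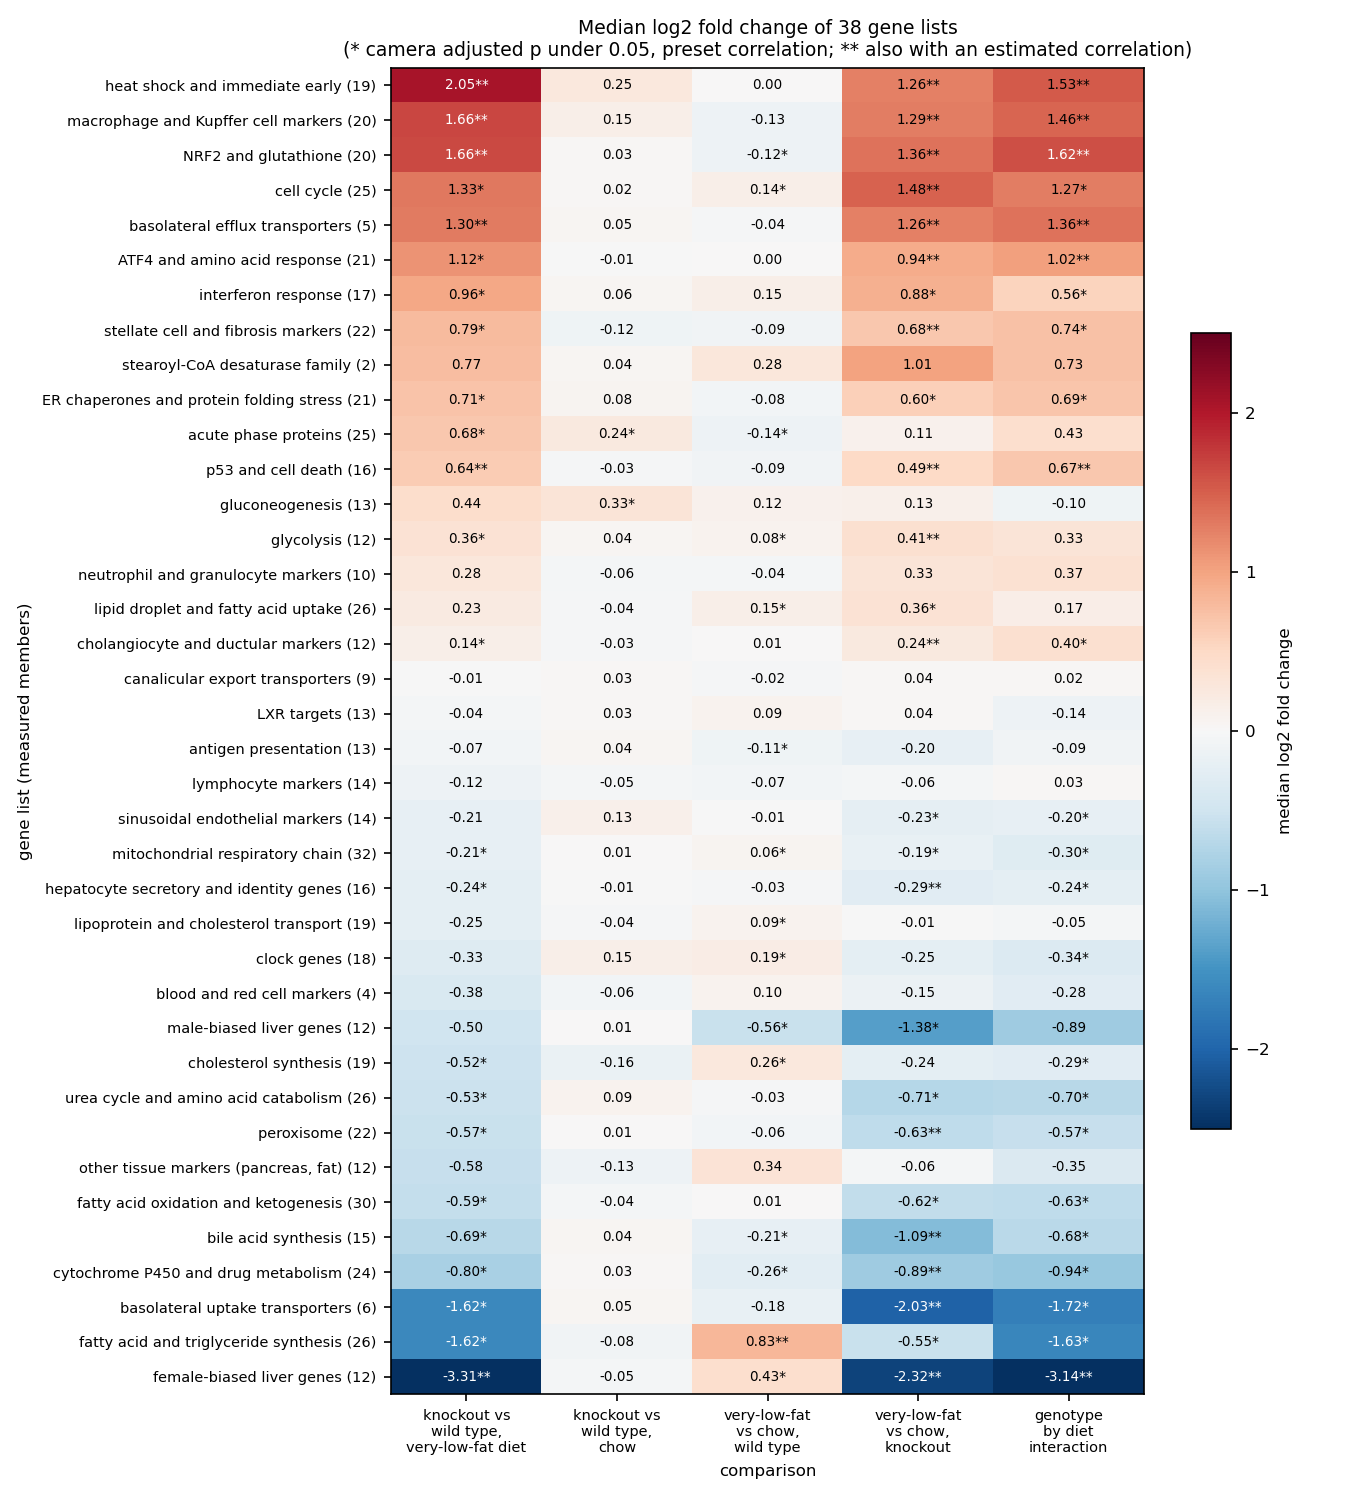
Median log2 fold change of the measured members (colour) of 38 gene lists (rows) in 5 comparisons (columns), 5 livers per group; the macrophage list had a median of 1.66 between knockout and wild type on the VLF diet. A single asterisk marks a camera call with the preset correlation and a double asterisk a call that also held with an estimated correlation.

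On chow Csad and Dnase2a had the largest called changes next to Scd1 (n = 5 and 5 livers). Csad, the cysteine sulfinate decarboxylase of taurine synthesis, fell 6.09-fold from 1202 ± 384 to 201 ± 91.0 (log2 change -2.61 ± 0.34, adjusted p = 0.00247). The probe set of the lysosomal nuclease Dnase2a fell 4.73-fold (-2.24 ± 0.35, adjusted p = 0.0117); it followed Csad from array to array and is not shown to read Dnase2a alone. The Ras exchange factor Rasgef1b rose (1.11 ± 0.16, adjusted p = 0.00649). The mTOR inhibitor Ddit4 rose 4.34-fold (2.12 ± 0.42, adjusted p = 0.026). Fatty acid and triglyceride synthesis genes showed no calls on chow, Fasn (-0.10) included.

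Limma called 532 genes on chow (2.92%), 223 up and 309 down, of which 15 changed 2-fold or more; with only the chow groups fitted it called 10. The circadian deadenylase Noct (1.58 ± 0.30, adjusted p = 0.0239), the transcription factor Cebpd (1.52 ± 0.31, 0.0292), Pfkfb3 (1.22 ± 0.26, 0.0305) and Tcim (1.08 ± 0.23, 0.0335) were also among the largest rises. Arrdc3 (-1.47 ± 0.31, 0.0305), Rnf186 (-0.85 ± 0.19, 0.0368) and 1810019D21Rik (-0.75 ± 0.16, 0.0298) completed the largest falls. Scd1, Csad, Dnase2a and Rasgef1b kept their calls whichever array was left out. Csad and Dnase2a are each read from a single probe set, of a kind that can read several transcripts. The fit without such probe sets could therefore not test them in any comparison. Ddit4, Noct, Cebpd, Pfkfb3, Tcim, Arrdc3, Rnf186 and 1810019D21Rik all lost theirs without wild-type chow array 1 (adjusted p = 0.0726 for Noct to 0.0967 for Rnf186), and all but Arrdc3 without knockout chow array 3 (0.0633 for Ddit4 to 0.0877 for Tcim). Wild-type chow array 4 ended the calls of Ddit4, Cebpd, Pfkfb3, Tcim, Arrdc3 and Rnf186 (up to 0.0816), wild-type chow array 2 that of Arrdc3 (0.0526). Knockout chow array 1 ended those of Pfkfb3, Tcim, Rnf186 and 1810019D21Rik (up to 0.0581), and array 4 those of Cebpd, Tcim, Rnf186 and 1810019D21Rik (up to 0.063). The count of 532 became 25, 225, 256, 69 and 815 without wild-type chow arrays 1 to 5 in turn, and 185, 1032, 36 and 59 without knockout chow arrays 1 to 4. It became 281, 290, 847 and 313 without wild-type VLF arrays 1, 2, 4 and 5, and 830, 314 and 315 without knockout VLF arrays 2, 4 and 5. Of the calls 41.9% were up, against 84.5% of 1497 calls with median scaling alone and 62.6% of 1819 calls with the deposited values in log2. Arrays centred on the hybridization controls gave 56 genes, kept 22 of the rises and 12 of the falls, and moved the median of all genes from -0.02 to -0.15.

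Preset genes were not called on chow: Scd2 (0.25), Cyp7a1 (0.04), Abcb11 (-0.19), Ppargc1a (0.33), Fgf21 (-0.18), Cpt1a (0.27) and Pck1 (0.40 ± 0.14, adjusted p = 0.106). Of 26 fatty acid and triglyceride synthesis genes limma called 0, with 1 up and 2 down at unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.967). Bile acid synthesis had 0 of 15 called by limma, 1 down at unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.741). Gluconeogenesis shifted up as a set (camera adjusted p = 0.00206; adjusted p = 0.876 with an estimated correlation), although limma called 0 of 13, with 6 up at unadjusted p under 0.05. Without knockout chow array 3, where the list's mean deviation was 0.47, camera gave gluconeogenesis adjusted p = 0.0115. Adjusted over the list alone 4 rose: Igfbp1 (1.73 ± 0.47), Tat (0.67 ± 0.19), Slc37a4 (0.53 ± 0.16) and Pck1. Acute phase proteins shifted up as well (camera adjusted p = 0.00206; adjusted p = 0.943 with an estimated correlation), with 0 of 25 called by limma, 5 up at unadjusted p under 0.05 and 1 up adjusted over the list alone. Their largest member by evidence was Orm1 (0.39 ± 0.11), and the camera call ended without knockout chow array 3 (adjusted p = 0.0931). That array read Lcn2 at 6727, against 211 ± 44.0 in the other 4 knockout chow livers. The actin 3' to 5' ratio averaged 2.25 in knockout and 2.70 in wild-type chow arrays (difference -0.451, two-sided exact permutation p = 0.00794, n = 5 and 5).

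In wild-type livers the VLF diet raised Elovl6, Fasn, Scd1 and Apoa4 (n = 5 and 5 livers). Elovl6 rose 4.82-fold (log2 change 2.27 ± 0.29, adjusted p = 0.000878) and Fasn 3.27-fold from 1171 ± 363 to 3982 ± 1808 (1.71 ± 0.26, adjusted p = 0.003). Scd1 rose 2.14-fold (1.09 ± 0.16, adjusted p = 0.00205) by its brightest probe set and 6.35-fold (2.67 ± 0.28, adjusted p = 0.000123) by the dimmer probe set, and apolipoprotein Apoa4, a gene induced by lipid flux, rose 4.81-fold (2.27 ± 0.22, adjusted p = 7.30e-05). Csad fell 6.71-fold (-2.75 ± 0.34), Dnase2a fell by 2.35 ± 0.35 and the secreted peptide gene Enho fell 5.43-fold (-2.44 ± 0.25).

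Limma called 287 genes (1.58%), 145 up and 142 down, with 24 up and 23 down by 2-fold or more; with only the compared groups fitted it called 169. The lysophospholipid transporter Mfsd2a (1.99 ± 0.35), the fatty acid binder Fabp5 (1.84 ± 0.31) and Dntt (1.51 ± 0.14, not called without probe sets that can read several transcripts) completed the largest rises. Cyp2c54 (-2.07 ± 0.29) and Fam25c (-1.93 ± 0.29) also fell, as did the early growth response gene Egr1 (-2.37 ± 0.51, adjusted p = 0.0296). The Egr1 call ended without wild-type VLF array 1, 2, 3 or 4 or wild-type chow array 1, 2, 4 or 5 (adjusted p up to 0.0829). The count of 287 became 146 and 129 without wild-type VLF arrays 1 and 4, and 136 and 176 without wild-type chow arrays 1 and 2. Of the calls 50.5% were up, against 66.9% of 178 with median scaling alone and 72.5% of 142 with arrays centred on the hybridization controls, which kept 65 of the rises and 31 of the falls. Preset genes not called were Scd2 (0.59), Srebf1 (0.57, adjusted p = 0.125), Cyp7a1 (-1.69 ± 0.48, adjusted p = 0.107), Slc10a1 (0.45), Abcb11 (-0.25), Cpt1a (0.36), Pck1 (0.12), Ppargc1a (0.08) and Fgf21 (0.14).

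Of 26 fatty acid and triglyceride synthesis genes 11 rose and 15 were not called (20 up and 1 down adjusted over the list alone), with Tkt (0.66 ± 0.08), Elovl6, Elovl5 (1.00 ± 0.14) and Fasn lowest in adjusted p. The list rose as a set with either correlation (camera adjusted p = 5.40e-22; adjusted p = 0.0266 with an estimated correlation), the only one of 15 called lists to hold. Lipid droplet and fatty acid uptake genes had 3 up of 26, 23 not called (4 adjusted over the list alone): Fabp2 (1.19 ± 0.17), Acsl5 (0.75 ± 0.12) and Fabp5. Lipid droplet genes as a set had camera adjusted p = 0.000577, and adjusted p = 0.131 with an estimated correlation. In bile acid synthesis Cyp7b1 (-1.22 ± 0.21) and Cyp27a1 (-0.69 ± 0.13) fell whichever array was left out. Bile acid synthesis genes as a set had camera adjusted p = 0.000728, and adjusted p = 0.181 with an estimated correlation. Drug-metabolizing P450 genes had 5 down, 2 up and 17 not called of 24 (13 down and 5 up adjusted over the list alone), with Ephx1 (-0.97 ± 0.11), Cyp2c54 and Cyp1a2 (-1.21 ± 0.18) down and Cyp3a44 (0.86 ± 0.14) up. Drug-metabolizing P450 genes as a set had camera adjusted p = 0.00117, and adjusted p = 0.3 with an estimated correlation. Cyp3a44 was also the only riser among 12 female-biased genes (4 adjusted over the list alone; camera adjusted p = 0.000396; adjusted p = 0.131 with an estimated correlation). Male-biased genes had 3 down of 12, 9 not called (7 adjusted over the list alone), Cyp7b1 and Gstp1 (-0.46 ± 0.09) among them. Male-biased genes as a set had camera adjusted p = 2.26e-05, and adjusted p = 0.0794 with an estimated correlation. Fatty acid oxidation had 0 of 30 called by limma, 2 up and 2 down at unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.292).

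Glycolysis had Khk (0.87 ± 0.11) and Pklr (1.36 ± 0.21) up of 12, 10 not called (2 adjusted over the list alone); its camera call (adjusted p = 0.043; adjusted p = 0.251 with an estimated correlation) ended in 6 of 20 omissions, most clearly without wild-type VLF array 4 (adjusted p = 0.103). It also ended with array weights, with only the compared groups fitted and without probe sets that can read several transcripts. Cholesterol synthesis had 0 of 19 called by limma, 5 up at unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.043; adjusted p = 0.724 with an estimated correlation), and its camera call ended with array weights and in 4 of 20 omissions, most clearly without wild-type VLF array 4 (0.517). Cell cycle genes had 0 of 25 called by limma, 4 up at unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.00516; adjusted p = 0.54 with an estimated correlation; 0.14 without that array). The lipoprotein list had Apoa4 and Apoc2 (0.71 ± 0.11) up of 19, 17 not called (4 adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.114 with an estimated correlation; 0.0515 without wild-type chow array 5). Clock genes had Per2 (0.84 ± 0.14) up of 18, 17 not called (4 adjusted over the list alone; camera adjusted p = 0.00407; adjusted p = 0.181 with an estimated correlation). Of antigen presentation genes H2-Eb1 (-0.58) fell. Cd74 and H2-Ab1 lost their calls without wild-type VLF array 1 or 4 or wild-type chow array 1 (adjusted p up to 0.052 and 0.0790), and H2-Ab1 without wild-type chow array 2 (0.0627). Antigen presentation genes as a set had camera adjusted p = 0.00223, and adjusted p = 0.251 with an estimated correlation; the call ended without probe sets that can read several transcripts. Acute phase proteins had 0 of 25 called by limma, 1 up and 9 down at unadjusted p under 0.05 and 8 down adjusted over the list alone. They gave camera adjusted p = 0.0244, and adjusted p = 0.724 with an estimated correlation (0.0533 without wild-type chow array 2), a call that also ended without such probe sets. NRF2 and glutathione genes as a set had camera adjusted p = 0.0399 (adjusted p = 0.251 with an estimated correlation). Their call ended in 4 of 20 omissions, most clearly without wild-type VLF array 2 (0.173), and with array weights, median scaling, median centring, only the compared groups fitted and without probe sets that can read several transcripts. Respiratory chain genes as a set had camera adjusted p = 0.00149, and adjusted p = 0.418 with an estimated correlation, and were not called without probe sets that can read several transcripts. Of 38 lists camera called 9 up and 6 down. Actin 3' to 5' ratios averaged 2.19 on the VLF diet and 2.70 on chow (difference -0.514, two-sided exact permutation p = 0.00794, n = 5 and 5).

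In knockout livers the VLF diet lowered Fasn and Elovl6, which it raised in wild type (n = 5 and 5 livers). Fasn fell by 1.42 ± 0.26 and Elovl6 by 1.58 ± 0.29 in log2. Sprr1a rose 82.4-fold (6.36 ± 0.20), Cbr3 37.7-fold (5.24 ± 0.16) and Cd14 29.1-fold (4.86 ± 0.30). Sult2a8 fell 82.7-fold from 4526 ± 824 to 55.0 ± 12.6 (-6.37 ± 0.19), and Cyp8b1 fell 25.6-fold (-4.68 ± 0.41). Apoa4 rose as in the wild type (2.87), and Enho fell (-2.54).

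Limma called 6323 genes (34.8%), 3101 up and 3222 down, with 651 up and 554 down by 2-fold or more. With arrays centred on the hybridization controls limma called 6407 up and 832 down; read from the same probe sets, all 3101 rises and 830 of the falls were still called. The surface antigen Ly6d (25.1-fold, 4.65 ± 0.24), Lcn2 (20.9-fold, 4.38 ± 0.72; 5.39 without knockout chow array 3) and Lgals3 (17.7-fold, 4.15 ± 0.16) completed the largest rises. Sult3a1 (at least 76.6-fold), Car3 (43.2-fold, -5.43 ± 0.32), Cyp2c54 (-5.05 ± 0.29) and Mup10 (28.6-fold, -4.84 ± 0.24) completed the largest falls. Preset genes Scd2 (2.18 ± 0.32), Ppargc1a (1.34 ± 0.27) and Fgf21 (0.94 ± 0.21) rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 16.2-fold (-4.02 ± 0.48), and Slc10a1 (-1.73 ± 0.16), Srebf1 (-1.24 ± 0.17), Abcb11 (adjusted p = 0.000103), Cpt1a (-0.56 ± 0.12) and Pck1 (-0.61 ± 0.14, adjusted p = 0.00241) fell. Arrays centred on the hybridization controls moved the median of all genes from -0.03 to 0.35, and the mean log2 of those controls was lower in knockout VLF than in knockout chow arrays (-0.37, two-sided exact permutation p = 0.0317, n = 5 and 5). The actin ratio averaged 1.82 and 2.25 (difference -0.425, two-sided exact permutation p = 0.00794).

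Bile acid synthesis genes fell in 13 of 15, 2 not called (13 down and 1 up adjusted over the list alone), led by Hsd3b7 (-1.47 ± 0.10), Slc27a5 (-1.52 ± 0.11) and Cyp7b1 (-2.48 ± 0.21). For bile acid synthesis camera gave adjusted p = 5.46e-07, and adjusted p = 0.0422 with an estimated correlation. All 6 basolateral uptake transporters fell, also adjusted over the list alone, Slco1b2 (-2.32 ± 0.17) and Slc22a7 (-2.66 ± 0.24) among them. For uptake transporters camera gave adjusted p = 4.62e-05, and adjusted p = 0.046 with an estimated correlation. Basolateral efflux rose in 3 of 5 (3 adjusted over the list alone): Abcc4 (2.86 ± 0.15), Slc51b (2.09 ± 0.14) and Abcc1 (1.26 ± 0.09). For efflux transporters camera gave adjusted p = 0.0018, and adjusted p = 0.0427 with an estimated correlation. Fatty acid and triglyceride synthesis had 12 down, 3 up and 11 not called of 26 (13 down and 3 up adjusted over the list alone), with Dgat2 (-1.57 ± 0.10) and Mlxipl (-1.46 ± 0.16) down and Pgd (2.69 ± 0.20) and Tkt (1.08 ± 0.08) up. Its camera call (adjusted p = 0.032; adjusted p = 0.478 with an estimated correlation) ended without knockout VLF array 2 (adjusted p = 0.0598) or knockout chow array 1 (0.0503). NRF2 and glutathione genes rose in 17 of 20, 1 (Gstt3, -0.56) fell and 2 were not called (the same adjusted over the list alone), with Gsr (1.40 ± 0.05), Srxn1 (3.89 ± 0.18) and Gstm3 (2.78 ± 0.18) up. For NRF2 and glutathione genes camera gave adjusted p = 1.36e-11, and adjusted p = 0.00115 with an estimated correlation. Macrophage markers rose in 17 of 20, 3 not called (18 adjusted over the list alone), led by Gpnmb (4.07 ± 0.18) and Cd68 (2.11 ± 0.13). For macrophage markers camera gave adjusted p = 2.96e-12, and adjusted p = 0.0422 with an estimated correlation. Stellate cell and fibrosis markers rose in 15 of 22, 7 not called (15 adjusted over the list alone), with Col1a2 (1.11 ± 0.12) and Timp1 (1.69 ± 0.13) up. For fibrosis markers camera gave adjusted p = 1.45e-06, and adjusted p = 0.046 with an estimated correlation. Drug-metabolizing P450 genes fell in 18 of 24, 1 (Ephx1, 0.53) rose and 5 were not called (21 down and 1 up adjusted over the list alone), Cyp2c37 (-3.82 ± 0.20) and Cyp2c50 (-3.22 ± 0.15) among them. For P450 genes camera gave adjusted p = 2.43e-09, and adjusted p = 0.0422 with an estimated correlation.

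Cell cycle genes rose in 20 of 25, 5 not called (21 adjusted over the list alone), Birc5 (2.94 ± 0.25) and Nusap1 (1.81 ± 0.14) among them. For the cell cycle camera gave adjusted p = 2.05e-11, and adjusted p = 0.0454 with an estimated correlation. The ATF4 and amino acid response rose in 15 of 21, 2 (Shmt2, -0.82; Atf5, -0.74) fell and 4 were not called (the same adjusted over the list alone), with Psat1 (3.94 ± 0.12), Atf3 (3.72 ± 0.14) and Nupr1 (3.47 ± 0.23) up. For ATF4 response genes camera gave adjusted p = 5.46e-07, and adjusted p = 0.0454 with an estimated correlation. ER chaperones rose in 16 of 21, 5 not called (17 adjusted over the list alone), Derl3 (2.18 ± 0.11) and Creld2 (2.78 ± 0.29) among them. For ER chaperones camera gave adjusted p = 1.89e-07, and adjusted p = 0.0863 with an estimated correlation. Peroxisomal genes fell in 17 of 22, 5 not called (18 adjusted over the list alone), Hacl1 (-2.45 ± 0.13) and Phyh (-1.18 ± 0.07) among them. For peroxisomal genes camera gave adjusted p = 8.97e-09, and adjusted p = 0.0454 with an estimated correlation. Fatty acid oxidation genes fell in 22 of 30, 3 (Pdk4, 3.24; Acot2, 1.12; Ehhadh, 0.47) rose and 5 were not called (24 down and 3 up adjusted over the list alone), with Fabp1 (-1.40 ± 0.12) and Eci1 (-1.19 ± 0.11) down. For fatty acid oxidation camera gave adjusted p = 1.09e-05, and adjusted p = 0.334 with an estimated correlation. Urea cycle and amino acid genes fell in 19 of 26, 1 (Ass1, 0.62) rose and 6 were not called (the same adjusted over the list alone), Otc (-1.62 ± 0.07) and Hpd (-1.37 ± 0.08) among the fallers. For urea cycle genes camera gave adjusted p = 2.25e-06, and adjusted p = 0.209 with an estimated correlation. Hepatocyte identity genes fell in 10 of 16, 1 (Alb, 0.07) rose and 5 were not called (the same adjusted over the list alone), with Fetub (-1.81 ± 0.13) and Cebpa (-1.72 ± 0.13) down. For hepatocyte identity genes camera gave adjusted p = 0.000873, and adjusted p = 0.0454 with an estimated correlation. Of 38 lists camera called 13 up and 12 down, 16 of them with an estimated correlation as well.

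The interaction compared the knockout effect on the VLF diet with that on chow over all 20 livers, 5 per group. Sprr1a had the largest positive interaction (log2 6.27 ± 0.29), followed by Cbr3 (5.20 ± 0.22), Cd14 (4.95 ± 0.43), Lcn2 (4.33 ± 1.01, larger without knockout chow array 3), Gpnmb (4.20 ± 0.26) and Lgals3 (4.20 ± 0.23). Gpnmb averaged 30.8 to 36.9 outside the knockout VLF livers, close to the array medians, so background limits the size of its changes in each comparison. Sult3a1 (-6.27), Sult2a8 (-5.28 ± 0.26), Car3 (-5.24 ± 0.45), Mup10 (-4.88 ± 0.34), Serpina6 (-4.82 ± 0.38) and Cyp2b13 (-4.23 ± 0.34) had the largest negative interactions, where the floor makes the Sult3a1 value a lower bound in size. Elovl6 (-3.85 ± 0.41), Fasn (-3.13 ± 0.37) and Cyp8b1 (-3.86 ± 0.58) responded to the diet in opposite or unequal ways in the genotypes. Csad (2.28 ± 0.47) and Dnase2a (1.94 ± 0.50) had positive interactions; Csad averaged 175 ± 49.0 in wild-type VLF, 201 ± 91.0 in knockout chow and 143 ± 56.0 in knockout VLF livers.

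Limma called 4401 genes for the interaction (24.2%), 2201 up and 2200 down. With arrays centred on the hybridization controls limma called 3028 up and 613 down; read from the same probe sets, 2121 of the positive and 612 of the negative interactions were still called. Of the preset genes Scd1 (-1.61 ± 0.23, with knockout signal close to the array medians, and -2.74 ± 0.40 by the dimmer probe set), Scd2 (1.59 ± 0.45), Srebf1 (-1.80 ± 0.24), Cyp7a1 (-2.33 ± 0.68), Slc10a1 (-2.18 ± 0.22), Cpt1a (-0.92 ± 0.17) and Pck1 (-0.73 ± 0.20, adjusted p = 0.0136) were called. Ppargc1a (1.26 ± 0.38, adjusted p = 0.0267) lost its call without knockout VLF array 3 or 5, knockout chow array 4, wild-type VLF array 1 or 2 or wild-type chow array 2 (adjusted p up to 0.0542). Abcb11 (-0.76 ± 0.23, adjusted p = 0.0295) lost it without knockout VLF array 1, 3 or 5, knockout chow array 5, wild-type VLF array 5 or wild-type chow array 3 (adjusted p up to 0.0577). Fgf21 was not called (0.80 ± 0.29, adjusted p = 0.0677), nor were Apoa4 (0.60, adjusted p = 0.238), Enho (-0.10, adjusted p = 1) and Fabp5 (0.16, adjusted p = 1), which responded to the diet in either genotype. Centring on the hybridization controls moved the median of all genes from -0.00 to 0.35.

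Fatty acid and triglyceride synthesis had 19 negative, 3 positive (Pgd, 1.49; Tkt, 0.43; Scd2) and 4 uncalled interactions of 26 (20 and 3 adjusted over the list alone), with Dgat2 (-1.71 ± 0.14) and Fads2 (-1.94 ± 0.24) negative. Synthesis of fatty acids and triglycerides gave camera adjusted p = 1.03e-07, and adjusted p = 0.0761 with an estimated correlation. Bile acid synthesis had 12 negative, 1 positive and 2 uncalled of 15 (the same adjusted over the list alone; camera adjusted p = 1.60e-05; adjusted p = 0.0505 with an estimated correlation), Cyp8b1 and Cyp7a1 among the negative. Basolateral efflux was positive in 4 of 5 (4 adjusted over the list alone): Abcc4 (2.60 ± 0.21), Slc51b (2.12 ± 0.20), Abcc1 (1.36 ± 0.13) and Abcc3 (1.07 ± 0.18). Efflux transporters gave camera adjusted p = 0.000167, and adjusted p = 0.021 with an estimated correlation. NRF2 and glutathione genes were positive in 16 of 20, negative in 1 (Gstt3, -0.98) and uncalled in 3 (16 and 2 adjusted over the list alone), with Gsr (1.53 ± 0.08) and Srxn1 (4.01 ± 0.26) positive. The NRF2 list gave camera adjusted p = 1.38e-13, and adjusted p = 0.00046 with an estimated correlation. Macrophage markers were positive in 17 of 20, 3 uncalled (17 adjusted over the list alone), Gpnmb and Ctss (1.81 ± 0.15) among them. Macrophage marker genes gave camera adjusted p = 5.84e-14, and adjusted p = 0.0208 with an estimated correlation. Heat shock and immediate early genes were positive in 12 of 19, negative in 1 (Hsph1, -1.34) and uncalled in 6 (14 and 3 adjusted over the list alone), Klf6 (2.45 ± 0.14) and Hspa1a (3.53 ± 0.22) leading. Heat shock genes gave camera adjusted p = 7.52e-06, and adjusted p = 0.0318 with an estimated correlation. The ATF4 list was positive in 12 of 21, negative in 2 (Atf5, -0.83; Shmt2, -0.57) and uncalled in 7 (14 and 2 adjusted over the list alone), led by Psat1 (3.94 ± 0.17) and Atf3 (3.68 ± 0.19). ATF4 response genes gave camera adjusted p = 1.32e-07, and adjusted p = 0.0494 with an estimated correlation. Female-biased genes were negative in 9 of 12, 3 uncalled (12 adjusted over the list alone), Cyp2b9 (-3.40 ± 0.13) and Cux2 (-2.87 ± 0.35) among them. Female-biased liver genes gave camera adjusted p = 3.88e-09, and adjusted p = 0.0189 with an estimated correlation. The p53 and cell death list was positive in 9 of 16, negative in 1 (Fas, -0.33) and uncalled in 6 (10 and 1 adjusted over the list alone), with Tnfrsf12a (3.44 ± 0.17) and Cdkn1a (3.62 ± 0.41) positive. The p53 list gave camera adjusted p = 2.69e-05, and adjusted p = 0.0197 with an estimated correlation. Camera called 11 lists up and 13 down for the interaction, 7 of them with an estimated correlation as well.

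Changes found only in the knockout on the VLF diet had to be called against each of the other 3 groups and for the interaction, in the same direction (5 livers per group). Sprr1a, Cbr3, Cd14, Lcn2, Gpnmb and Lgals3 led the risers, with Cbr3 at 1258 ± 384 in knockout VLF livers and 28.5 ± 3.80, 29.1 ± 1.80 and 32.6 ± 5.70 in the others. Lcn2 reached a deposited value of 6727 in knockout chow array 3 as well, beside a deposited knockout VLF mean of 8671. Sult3a1, Sult2a8, Car3, Mup10, Serpina6 and Cyp2b13 led the fallers, with Car3 at 267 ± 190 against 9293 ± 402 in wild-type VLF livers. The rule does not require the other 3 groups to be alike. Sult2a8 also fell with the VLF diet in wild type (-1.09 ± 0.19, limma adjusted p = 0.0064). The set held 3679 genes (20.2%), 1911 up and 1768 down (2678 up and 477 down with arrays centred on the hybridization controls), with 501 up and 359 down by 2-fold or more. In simulated groups without differences limma called 0 genes in each comparison, with 841 to 873 genes at unadjusted p under 0.05. The simulated noise was independent between probe sets, so shifts shared by many genes of an array were not covered.

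**Figure D3:**
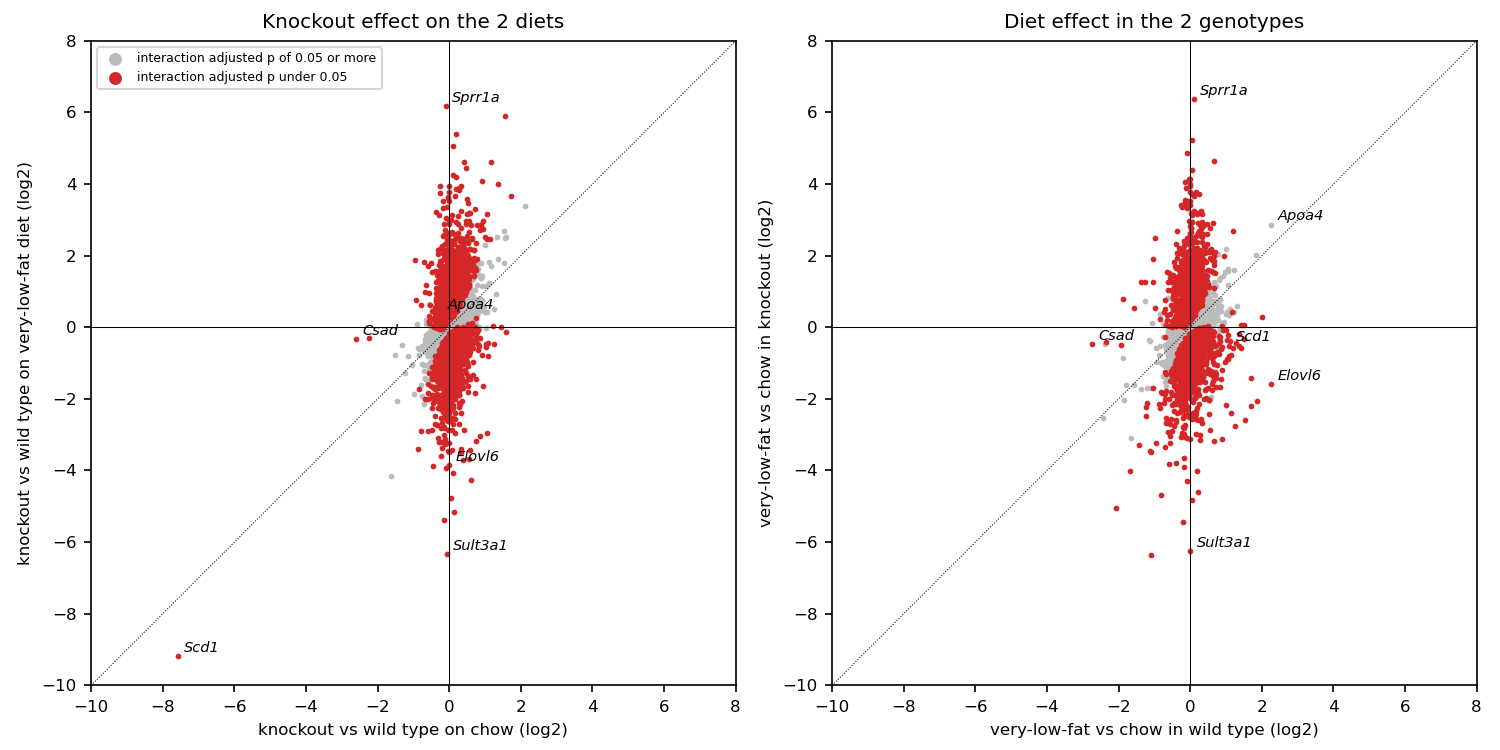
Log2 fold change of 16187 genes for knockout versus wild type on chow (x axis) against the VLF diet (y axis), and for VLF versus chow in wild type against knockout, each from 5 livers per group; red marks the genes called for the interaction. Pearson r over genes was 0.35 and 0.16.

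Scd1 was the extreme of the knockout effects on chow and on the VLF diet, which correlated across 16187 genes, not independent replicates, at Pearson r = 0.35 and Spearman rho = 0.38 (r = 0.33 without Scd1). With any array left out that r lay between 0.256 (without knockout chow array 3) and 0.38 (without wild-type VLF array 4). The actin 3' to 5' ratio was also lower in knockout arrays on either diet (-0.362 on the VLF diet, -0.451 on chow). Similar changes on either diet are therefore not shown to come from the knockout alone. Genes that rose in the knockout on either diet numbered 103 in common against 42.7 for independent lists, and those that fell 161 against 71.0. Opposite calls were fewer than for independent lists, with 37 up on chow and down on the VLF diet against 51.3, and 9 the other way against 59.2. These counts rest on the 532 genes called on chow, a number that ranged from 25 to 1032 over the omissions. Diet effects in wild type and knockout correlated across the same genes at r = 0.16 and rho = 0.15, with Apoa4 and Fabp5 raised in each and Enho lowered in each. They shared 40 genes up (24.7 for independent lists) and 84 down (25.1), while 52 rose in wild type and fell in knockout (25.7), Fasn and Elovl6 among them, and 27 did the reverse (24.2). All numbers for independent lists were taken over 18193 genes. Of these 2006 lay at the floor everywhere and could not be called, so the numbers are somewhat low. An excess as small as 27 over 24.2 is therefore not shown.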

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

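The tests of cell composition, actin ratio, hybridization-control scaling, swapped label, mixed sample, Csad with Dnase2a, glucocorticoid-induced genes and flanking DNA were chosen after the result was seen, while those of acute phase proteins in a single array and array splits were set before their values were seen. Single arrays were marked when 1 of 5 values of a named gene or array measure stood far from the other 4 in its group (Dixon's gap over range), which by chance marks about 1 in 20; 21 of 208 such tests were marked. A difference in the knockout effect between diets and the count of changed probe sets without a gene name were marked as well.

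Sprr1a, Cbr3 and many other genes changed in the knockout on the VLF diet, and 4401 had an interaction. A lower share of hepatocytes with an equal rise of every other cell type would raise endothelial and lymphocyte markers as well. Endothelial markers differed by -0.07 in knockout VLF livers (two-sided exact permutation p = 0.429, n = 5 and 5) and lymphocyte markers by -0.07 (p = 0.468). Macrophage minus endothelial markers were higher by 1.933 log2 (two-sided exact permutation p = 0.00794). These values argue only against an equal rise, not against unequal shifts of cell types. The marker changes were known when the test was chosen, so it is no independent support. More degraded RNA in the knockout VLF arrays is argued against by the actin 3' to 5' ratio, which was not higher there (difference -0.3621). The GAPDH control's ratio differed by -0.024 (two-sided exact permutation p = 0.508). On chow the GAPDH ratio differed by -0.187 between genotypes, and for the diet by -0.239 in wild type and -0.076 in knockout (exact permutation p = 0.00794, 0.00794 and 0.0159). A difference in RNA quality between the groups therefore stays open. Arrays centred on the hybridization controls gave 5359 genes and kept 3406 of 3487 rises but 1000 of 4183 falls, so a shift of scale could underlie part of the falls and stays open for them. Part of the marker rises could still come from composition. Neutrophil markers rose by a mean of 0.86, stellate markers by 0.70 and cholangiocyte markers by 0.53, and hepatocyte identity genes fell by 0.38. No measurement here separates cell number from expression per cell.

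Lcn2 in knockout chow array 3 read 12.68 in log2 against 7.31 to 7.96 in the other 4, and the same array stood apart for Apoa4 (11.032), Arrdc3 (6.8703), Car3 (12.571), Cyp2b13 (10.21), Lgals3 (8.3303), Ly6d (6.8123), Rasgef1b (7.9163) and Sult2a8 (11.579). Its position was 0.1621 between the mean of the other 4 knockout chow arrays (0) and the knockout VLF mean (1). Genes of that axis were called with this array counted as chow, which favours a low position. The other 4 arrays lay at -0.0463 to -0.023 against means that include this array, so these values are not its spread. The largest principal component does not use that choice of genes. There the array lay at -2.61, against 15.0 to 19.1 in the other 4 and -61.4 to -51.5 in knockout VLF arrays. That argues against a swapped label. A mixed sample is argued against by unequal implied shares, 77.03% from Lcn2 but -0.284% from Sprr1a and 0.833% from Cbr3. The acute phase list had a mean deviation of 1.411 log2 in that array (median 0.768), with 22 of 25 members above all other 4 arrays. The mean lay above all 10000 random lists. Lcn2, by which the array was marked, belongs to the list. The random lists were matched on expression but not on shared regulation, so a list that moves together exceeds them easily. Members not used in the marking were high too, such as Saa2 (5.06), Orm2 (4.32) and Saa1 (3.85), while Il1rn was not (-0.09). The values go with an acute phase response in that liver but are no independent test of it. Whether infection, injury or handling may have caused such a response stays open.

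Csad and Dnase2a fell by similar amounts wherever they fell, and wild-type chow array 4 stood apart for each (9.0658 and 9.0402 in log2). Across 20 arrays their deviations from group means correlated at Pearson r = 0.9527 (permutation p = 2.00e-05) and Spearman rho = 0.964 (p = 1.00e-05), and at r = 0.944 without wild-type chow array 4 and wild-type VLF array 3. No other gene of 16187 came above 0.783. The Dnase2a probe set could read Csad RNA, which nothing in the tables argues against. Only 1 probe set reads Dnase2a, and it is of a kind that can read several transcripts, so the question stays open.

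The glucocorticoid-induced list, drawn up after the genes raised on chow were seen, shifted up in the knockout on chow (camera p = 3.325e-06; p = 0.0726 with an estimated correlation), with Errfi1 (0.75 ± 0.10) its only call. Since its members were chosen in view of the same comparison, this is no independent test, and the cause stays open. Genes called alike in the knockout on both diets lay within 20 Mb of Scd1 in 1.894% of cases, Scd1 included. That argues against flanking DNA as the main source, an outcome made likely by the window, which held 278 genes beside 15874 elsewhere. Genes called on at least 1 of the diets were more frequent there (odds ratio 1.31, two-sided Fisher exact p = 0.0292).

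Chance is an unlikely source of the counts that follow, since in 1 of 100 splits or regroupings, the real one, as many genes were called. Scd1, the deleted gene, adds to the real knockout counts in advance. The other splits mix livers of unlike groups, which widens the spread and lowers their counts. Their counts are therefore no estimate of false calls. The real grouping gave 7481 genes for knockout versus wild type on the VLF diet (highest other 1682), 10 on chow (highest other 0), 169 for the diet in wild type (0) and 5777 for the diet in knockout (1116), each fitted by limma on the 10 arrays compared. It gave 4401 for the interaction (highest other 7) and 3679 for the set found only in the knockout on the VLF diet (0). The counts of 532 on chow and 287 for the diet in wild type, from the fit of all 20 arrays, were not split. Chance was therefore not weighed for them in this way and is not excluded.

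Other single values were Abcb11 in wild-type chow array 2 (11.661), Cd14 (10.11) and Fabp5 (11.408) in knockout VLF array 2, Fam25c in knockout chow array 2 (8.9156) and Fgf21 in wild-type VLF array 5 (5.8572). Gpnmb in wild-type VLF array 1 (5.0234), Lgals3 in array 2 (7.005), Sult1e1 in array 3 (4.8865) and Ly6d in array 4 (6.9631) stood apart too. Wild-type VLF array 4 had 28.141% of probe sets under the floor, against 27.2% to 27.4% in the other 4. Of probe sets without a gene name, 1785 changed between knockout and wild type on the VLF diet, 543 up and 1242 down.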

How the results depend on the processing

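Scd1 was lower in the knockout under every alternative, at -9.24 to -9.13 log2 on the VLF diet and -7.67 to -7.41 on chow with any array left out. Knockout versus wild type on the VLF diet gave 6747 to 8066 genes over the omissions and 1317 with a 2-fold minimum. The diet in knockout gave 5789 to 6661 (1205 with that minimum), the interaction 4120 to 4593 (1175) and the set found only in the knockout on the VLF diet 3428 to 3938 (860). On chow the 532 genes ranged from 25 to 1032 over the omissions; they were 1263 among brighter probe sets, 1497 with median scaling and 1497 with median centring, 937 with a floor at 1, 15 with a 2-fold minimum and 10 with only those groups fitted. The 287 genes of the diet in wild type ranged from 129 to 357, and were 178 with median scaling, 178 with median centring, 505 with array weights, 169 with only those groups fitted and 47 with a 2-fold minimum. Alternatives chosen after seeing the data gave 1819 genes on chow with the deposited values in log2, 56 with hybridization-control centring and 26 without wild-type VLF array 3 and knockout chow array 3; the diet in wild type gave 142 with that centring. Signal over background limits what a dim probe set can show, and the cause of these differences was not tested.

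Lists called fell with an estimated correlation from 24 to 6 for knockout versus wild type on the VLF diet, 2 to 0 on chow (camera, 7 at unadjusted p under 0.05), 15 to 1 for the diet in wild type, 25 to 16 in knockout and 24 to 7 for the interaction. On chow 6 lists were called with median scaling and 6 with median centring, and 4 each with array weights, without probe sets that can read several transcripts and with the mean of a gene's probe sets; the omissions gave 2 to 4. H2-DMa turned from 0.30 to -0.10 with the mean of its probe sets for knockout versus wild type on the VLF diet, and Mgll to 0.12 in the interaction without probe sets that can read several transcripts. Genes called in both knockout comparisons had an odds ratio near Scd1 of 1.10 (two-sided Fisher exact p = 0.809). It was 1.31 for genes called in either in place of both (two-sided Fisher exact p = 0.0292; 154 of 278 near Scd1 and 7724 of 15874 elsewhere).

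Replicate numbers did not pair samples: deviations of the 30 same-number pairs correlated at -0.248 to 0.234 (mean -0.0118). As a block they gave 260 genes on chow, 224 for the diet in wild type and 7401 for knockout versus wild type on the VLF diet. The camera call of glycolysis for the diet in wild type ended with the block (adjusted p = 0.0569).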

Other observations

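Lpl (log2 change 3.43 ± 0.20), Cidea (2.78 ± 0.21), Cidec (1.92 ± 0.17) and Hilpda (1.39 ± 0.16) rose with the VLF diet in knockout livers (limma, n = 5 and 5), within a list of 26 with 13 up, 8 down and 5 not called (13 up and 9 down adjusted over the list alone). The list's camera call (adjusted p = 0.0455; adjusted p = 0.272 with an estimated correlation) ended in 4 of 20 omissions, most clearly without knockout VLF array 1 (adjusted p = 0.0659), and also among brighter probe sets, with median scaling and with median centring. Interferon response genes rose in 13 of 17, 4 not called (13 adjusted over the list alone), with Oas1a (1.46 ± 0.13) and Rsad2 (2.92 ± 0.33) up (camera adjusted p = 4.28e-05; adjusted p = 0.272 with an estimated correlation).

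The glucocorticoid list and its test were chosen after the genes raised on chow were seen, and Xist was looked up after the arrays were seen. On chow 17 of its 18 genes had a positive change in the knockout, with a median of 0.43; Dusp1 (1.14 ± 0.32), Cebpb (0.85 ± 0.23) and Tat (0.67 ± 0.19) were not called. The choice of members in view of the same comparison makes this a description only, and supports no explanation.

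Xist, which marks the inactive X chromosome, read 11.9 in wild-type VLF array 3 and 1095 to 1915 in the other 19 arrays, while the Y-linked Kdm5d, Uty and Eif2s3y lay at background in all 20. In those 19 arrays Xist signal without Y-linked signal marks female livers. Genes that escape X inactivation were mostly low in wild-type VLF array 3 as well, by their brightest probe sets. Deposited values were 1479 for Ddx3x (1854 to 3366 in the other 19 arrays) and 571 for Eif2s3x (661 to 929). They were 180 for Kdm6a (204 to 654), 82.25 for Pbdc1 (88.55 to 446.8) and 24.63 for Mid1 (24.78 to 60.34). Kdm5c and 5530601H04Rik lay within the range of the other arrays. What caused the missing Xist in that array was not tested. Near Scd1, on the GRCm38.p6 assembly, 5 of 278 genes were called alike in the knockout on both diets, against 259 of 15874 elsewhere (two-sided Fisher exact p = 0.809). Next to Scd1 they were Lipa (-0.41 on chow, -0.42 on the VLF diet), Cox15 (0.49, 0.33), Htr7 (-0.34, -0.35) and Gm9895 (-0.29, -0.64). The chow call of Lipa ended in 13 of 20 omissions, most clearly without knockout chow array 3 (limma adjusted p = 0.117).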
